A study of Homo sapiens with 4 samples.

How the data were processed

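RNA-seq of total RNA was compared between JJN3 cells transduced with a WNK1 short hairpin RNA (shRNA) and JJN3 cells transduced with the NS shRNA, with 2 libraries in each group, per the labels. The title of shWNK1 replicate 2 spells the gene shNWK1, which was read as a misspelling. The deposited table holds raw counts per gene, made by the authors with featureCounts v2.0.0 on the GENCODE v34 primary assembly annotation, per the file headers. Fragments of paired reads were counted by gene without regard to strand (strand setting 0), with a mapping quality of at least 20, both ends mapped and chimeric pairs left out, per the file headers. The command recorded there does not ask for reads that map to several places or overlap several genes to be counted. Reads were trimmed with Trimmomatic and aligned with STAR to hg38, per the submitters' processing notes, which give no version of either. Because strand was not used, reads of overlapping genes on opposite strands cannot be told apart where both cover the same bases. Genes with near-identical copies include some immunoglobulin constant, HLA and histone genes, HSPA1A and HSPA1B, and ribosomal protein genes with processed pseudogenes. Such genes lose reads to the mapping quality minimum, so their levels are uncertain.

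The table lists 60728 genes. One gene, broken over 3 lines with values that do not line up with the columns, and 45 Y copies of pseudoautosomal genes with 0 counts were left out, leaving 60682, of which 60369 identifiers matched a symbol. Coordinates are those of the table, on hg38. Gene types and 3′ UTR sequences came from GENCODE v29, which holds 58495 of the identifiers. Total counts were 16973521 and 20164122 in the shWNK1 libraries and 17491537 and 17392619 in the NS libraries, so that 3 counts, about the 95% upper limit when 0 are seen, correspond to 0.149 to 0.177 CPM (counts scaled to a common library size). Intervals for shares of counts are 95% Wilson intervals, those for shares of genes are 95% exact Clopper-Pearson intervals, and both cover counting error only, since reads copied by PCR are not independent molecules.

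The tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (14864 genes), scaled by TMM factors, fitted with glmQLFit (robust) and tested two-sided with glmQLFTest, with shWNK1 over NS as the only term and 2 residual degrees of freedom. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. Levels are CPM with TMM-scaled library sizes, given as mean ± SD (n = 2), and standard errors (SE) are those the quasi-likelihood F statistic gives. The labels do not say whether the replicates are separate cultures or transductions, so p-values measure only the spread between these libraries, which may be technical.

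The 35 gene lists include WNK kinases and chloride cotransport, the osmotic and volume response, autophagy, lysosome, ER chaperones and the unfolded protein response, the ATF4 response, plasma cell identity, MAF-associated myeloma genes, MYC targets and ribosome biogenesis, S phase, G2/M phase, interferon-stimulated genes, class I antigen presentation, NF-κB targets, ERK immediate and feedback genes, the ERK5 cascade, adhesion and migration, apoptosis, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, nuclear and mitochondrially encoded respiratory chain genes, cytosolic ribosomal proteins, the proteasome, heat shock, NRF2 targets, replication-dependent histones, immunoglobulin constant genes, and markers of T and NK, myeloid, mature B, erythroid and stromal or epithelial cells. The 31 lists with at least 5 tested members were tested two-sided with camera (limma 3.58.1) on voom values with a preset between-gene correlation of 0.01 and Benjamini-Hochberg adjustment over those lists.

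The named genes were WNK1; a panel fixed whatever its result (including WNK2, WNK3, WNK4, OXSR1, STK39, SLC12A2, MAF, CCND2, ITGB7, IRF4, PRDM1, XBP1, SDC1, TNFRSF17, MYC, TFEB and SQSTM1); the 6 largest rises, the 6 largest falls and the 6 smallest p in each direction among called genes with a mean of at least 5 CPM in the higher group and both shWNK1 libraries on one side of both NS libraries, leaving out clone-type names and pseudogenes; and up to 2 rising and 2 falling members of each called list, by smallest p. This gave 70 genes, and not all of them are described. Another 94 genes were chosen after their values were seen: up to 2 rising and 2 falling members of each list that was not called, by smallest p, and genes of a few families described among the closing observations.

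Alternatives tried were the DESeq2 1.42.0 Wald test, limma-voom, RLE and upper-quartile factors, no low-count filter, a filter of 1 CPM in 2 libraries, the replicate number as a block, leaving out immunoglobulin and mitochondrially encoded genes, a test against a fold change of 1.5 (glmTreat), leaving out each library in turn, and for lists an estimated correlation and fry. Chosen after seeing the data were fits limited to genes with a searched 3′ UTR of at least 50 bases and to those lacking the word AGTATC. Also chosen then was the removal of trends in gene length and GC content (loess, span 0.5, per library). Transcripts whose annotation holds the letters NF, a mark of incomplete ends, were not searched here or in the word search below. This also left out genes with NF in their symbol, such as NFKB1, TNFAIP3 and TNFRSF17, whatever their 3′ UTR. Of 17 tested NF-κB targets, 11 were searched.

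Each 7-base word found in the 3′ UTRs of at least 50 genes was tested for its association with the ranked log2 fold changes (as normal scores) by linear regression, with 3′ UTR length, 3′ UTR GC content and expression as piecewise linear covariates, over genes with a mean of at least 1 CPM and a 3′ UTR of at least 50 bases, using the principal annotated transcript (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). The edgeR fit was tested on simulated data drawn from these libraries' means and dispersions for the shWNK1 against NS comparison. Among 14864 genes, 50 were changed at each size, all of them with a mean of at least 5 CPM. The fit recovered 44% at 1.25-fold, 80% at 1.5-fold, 100% at 2-fold and 100% at 4-fold, and it called 3 of 14664 unchanged genes. Recovery in genes of lower level was not simulated. In the same simulation a list of 30 genes shifted by 0.4 (log2) gave a camera adjusted p of 9.1e-93 with the preset correlation and 0.0557 with an estimated one. With 2 libraries per group the estimated correlation thus missed a shift of that size. The simulated genes varied independently, so the simulation cannot show whether the preset correlation is high enough for real lists. None of the 30 unshifted lists was called.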

Results

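Transcript levels were measured by RNA-seq in JJN3, an established human multiple myeloma (plasma cell cancer) line, after transduction with an shRNA against WNK1 or with the NS shRNA, which served as the control. WNK1 is a kinase of the with-no-lysine family that phosphorylates the kinases OXSR1 and STK39, regulators of the SLC12 chloride cotransporters. The 4 libraries held 16973521 and 20164122 counts (shWNK1) and 17491537 and 17392619 counts (NS), with 21465 to 23575 genes having at least 1 count. The shWNK1 libraries differed from each other by a chi-square of 3 per degree of freedom and the NS libraries by 6.18, where 1 would be counting noise. Libraries of different groups differed by 40.9 to 48.2. The first principal component, with 64.8% of the variance, separated the groups, and the second, with 20.6%, separated the NS libraries from each other. Mitochondrially encoded transcripts made up 5.82% (95% interval 5.81 to 5.83) and 6.02% (6.01 to 6.03) of the counts in the shWNK1 libraries and 4.93% (4.92 to 4.94) and 4.58% (4.57 to 4.59) in the NS libraries.

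WNK1 itself (ENSG00000060237.17, chromosome 12, 752579 to 911452, plus strand, hg38) was counted 325 and 403 times in the shWNK1 libraries and 4911 and 4148 times in the NS libraries. Its level was 19.1 ± 0.688 CPM against 267 ± 30.3 CPM (mean ± SD, n = 2 libraries each), 13.9-fold lower in shWNK1 cells (log2 fold change -3.80, SE 0.085, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.2e-25). The direction was the one the labels call for.

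The comparison asked which transcripts differ between cells carrying the WNK1 hairpin and NS cells. Transcripts of chaperones, MYC targets, replication genes and sterol enzymes were lower in shWNK1 cells, and those of NF-κB targets and autophagy genes were higher. These are camera calls with a preset correlation, and with an estimated correlation 0 lists were called. Among single genes, the chemokine CXCL8 rose 7.83-fold and the cell cycle inhibitor CDKN1A rose 3.41-fold, while the ER disulfide isomerase PDIA4 fell 4.62-fold and the mitochondrial chaperonin HSPD1 fell 3.55-fold. Of 14864 genes tested, 2755 rose and 3005 fell (edgeR, Benjamini-Hochberg), and 442 and 386 of these changed at least 2-fold. Both shWNK1 libraries lay on one side of both NS libraries for 68.4% of tested genes, where chance gives 33.3%. Without shWNK1 replicate 1 there were 1663 rises and 1964 falls, and without shWNK1 replicate 2 there were 1632 and 2034. Without NS replicate 1 there were 2685 and 3024, and without NS replicate 2 there were 2778 and 2821. Against a fold change of 1.5, 303 genes rose and 353 fell. The 6-base word AGTATC was present in the annotated 3′ UTR of 32.0% of falling genes (854 of 2668 searched, 95% interval 30.2 to 33.8), 18.3% of genes not called (1018 of 5548, 17.3 to 19.4) and 16.1% of rising genes (370 of 2305, 14.6 to 17.6). Genes that rose or fell and carry it are named below as carriers of the word. Genes not so named lack it or were not searched. Those not searched include MYC, NFKB1, TNFAIP3, RPL24, H2BC12 and the immunoglobulin constant and mitochondrially encoded genes named here.

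**Figure D1:**
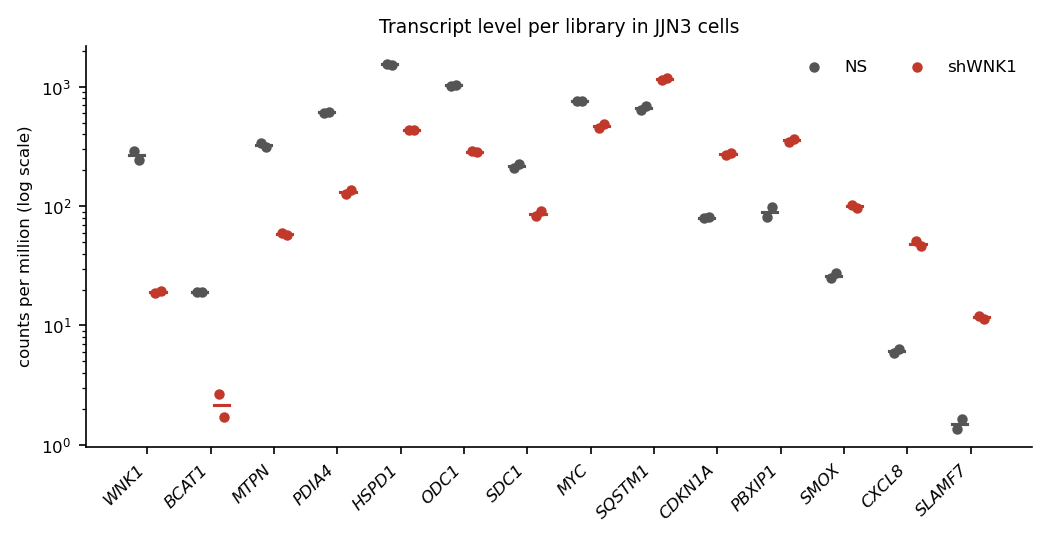
Level of 14 named genes in each library, in CPM on a log axis; points are libraries, 2 per group, and bars are group means. WNK1 stood at 19.1 CPM in shWNK1 against 267 CPM in NS cells, and for every gene plotted both shWNK1 points lie on one side of both NS points.

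The 6 largest rises among well-measured genes were those of CXCL8, SLAMF7, S100A9, TULP3, POU2F3 and SPIB. CXCL8 (chromosome 4, 73740541 to 73743716) rose from 6.15 ± 0.326 to 48.3 ± 3.25 CPM (log2 fold change 2.97, SE 0.133, edgeR adjusted p = 3.6e-18). SLAMF7, a surface receptor of plasma cells, rose 7.77-fold to 11.7 ± 0.539 CPM (log2 2.96, SE 0.245). S100A9, a calcium-binding protein abundant in myeloid cells, rose from 1.18 ± 0.839 to 8.82 ± 1.77 CPM (log2 2.90, SE 0.323; 2.32 without NS replicate 1 and 3.91 without NS replicate 2). TULP3 (log2 2.84; 3.63 without NS replicate 1), the octamer factor POU2F3 (2.56) and the B-cell ETS factor SPIB (2.19) also stood at 5.13 to 21.4 CPM in shWNK1 cells and at 1.12 to 2.97 CPM in NS cells. By smallest p, the rising genes were CDKN1A (chromosome 6, 36676460 to 36687337; log2 1.77, SE 0.065, edgeR adjusted p = 2.7e-20), PBXIP1 (2.00), CXCL8, the spermine oxidase SMOX (1.92), the mRNA-decay factor ZFP36L1 (1.75) and the mitochondrial ribosomal RNA MT-RNR2 (1.16).

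After WNK1, BCAT1, MTPN, EPHB2 and PDIA4 were among the largest falls. BCAT1, a branched-chain amino acid transaminase (chromosome 12, 24810024 to 24949101), fell from 19.1 ± 0.0184 to 2.17 ± 0.661 CPM (log2 -3.15, SE 0.207, edgeR adjusted p = 6.3e-14). MTPN, the actin-capping regulator myotrophin, fell from 326 ± 18.7 to 58.6 ± 1.47 CPM (log2 -2.48, SE 0.068). The ephrin receptor EPHB2 fell by 2.34 on the log2 scale, and PDIA4 (chromosome 7, 149003062 to 149028662) fell from 611 ± 3.61 to 132 ± 6.49 CPM (log2 -2.21, SE 0.061, edgeR adjusted p = 1.0e-23). Smallest p among falls went to WNK1, MTPN, PDIA4, HSPD1 (log2 -1.83), the polyamine enzyme ODC1 (-1.85) and the tropomyosin TPM4 (-1.91). BCAT1, MTPN, PDIA4, HSPD1, ODC1, TPM4 and WNK1 were carriers of the word AGTATC, and EPHB2 was not.

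Within the WNK and chloride cotransport list, the kinase SGK1 rose 3.56-fold (log2 1.83, SE 0.156, edgeR adjusted p = 3.0e-11). OXSR1 rose by 0.23 on the log2 scale (SE 0.068, edgeR adjusted p = 0.0080; 0.248 without shWNK1 replicate 2). STK39 fell by 0.22 (SE 0.080, edgeR adjusted p = 0.030), a call that ended with DESeq2 (0.0773), with upper-quartile factors (0.0766), and without shWNK1 replicate 1 (0.0951), shWNK1 replicate 2 (0.307) or NS replicate 1 (0.191). The sodium-potassium-chloride cotransporter SLC12A2 was at 47.0 ± 0.277 CPM in shWNK1 and 42.2 ± 4.47 CPM in NS cells (edgeR adjusted p = 0.207; 0.0328 without NS replicate 1). WNK2 was at 26.6 ± 1.49 and 26.4 ± 3.52 CPM (edgeR adjusted p = 0.937). WNK3, with 2 and 3 counts in shWNK1 and 5 and 2 in NS libraries, and WNK4, with 0 and 5 counts in shWNK1 and 0 and 0 in NS libraries, were too low to test. Of the 15 tested members of this list 5 rose, 2 fell and 8 were not called (5 and 2 adjusted over the list alone). Without NS replicate 1 there were 8 rises, and there was 1 fall without either shWNK1 library or NS replicate 1. Of 11 tested genes of the osmotic and volume response, 4 rose and 4 fell (4 and 4 adjusted over the list alone). The rises included the amino acid transporter SLC38A2 (log2 1.21), and the falls included the volume-regulated channel subunit LRRC8A (-0.63), a carrier of the word. The falls numbered 2 without shWNK1 replicate 1. Neither list was called by camera (adjusted p = 0.396 and 0.640).

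MYC targets and ribosome biogenesis genes were the most uniformly lower list. Of 34 members, 32 fell, 0 rose and 2 were not called (33 fell adjusted over the list alone), with a median log2 fold change of -0.51 (camera adjusted p = 5.9e-19; adjusted p = 0.253 with an estimated correlation). ODC1 and HSPD1 were its leading members, both carriers of the word, and the nucleolar protein NCL, another carrier, fell by 0.59. MYC itself fell from 756 ± 0.0504 to 469 ± 22.9 CPM (log2 -0.69, SE 0.057, edgeR adjusted p = 1.6e-11; 3′ UTR not searched). Among cytosolic ribosomal proteins, 50 of 77 fell, 0 rose and 27 were not called (54 fell and 1 rose adjusted over the list alone), with a median of -0.22 and with RPL15 (-0.36) and RPL24 (-0.39) as examples (camera adjusted p = 4.8e-11; adjusted p = 0.735 with an estimated correlation and 0.213 with fry). The NS libraries differed: the median was -0.30 with 69 falls without NS replicate 1 and -0.11 with 35 falls and 3 rises without NS replicate 2. Without shWNK1 replicate 1 and replicate 2 there were 19 and 28 falls.

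Replication and mitotic genes were lower for the most part. In the S phase list 27 of 41 members fell, 4 rose and 10 were not called (29 and 5 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 1.1e-07; adjusted p = 0.253 with an estimated correlation). The replicative helicase subunit MCM4 fell 2.79-fold (log2 -1.48) and the chromatin factor ATAD2 fell 1.76-fold (-0.82), both carriers of the word, while cyclin CCNE2 (0.56) and the transcription factor E2F1 (0.37) rose. G2/M genes included 21 falls, 3 rises and 17 members not called among 41 (22 and 3 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 1.6e-04; adjusted p = 0.296 with an estimated correlation). Cyclin CCNA2 (log2 -1.06) and the mitotic kinase PLK1 (-0.83) fell, and the cytokinesis genes ANLN (0.62) and KIF23 (0.45) rose. Of 14 replication-dependent histone genes, 3 rose, including H2BC12 (0.72), and 1 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.420). The fall was not called with any library left out, and 1 rise was called without shWNK1 replicate 2.

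Most ER chaperone and heat shock transcripts fell. Of 27 ER chaperone and unfolded protein response genes, 16 fell, 1 rose and 10 were not called (16 and 1 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 3.6e-07; adjusted p = 0.257 with an estimated correlation). HSPA5, the ER chaperone BiP, fell 1.91-fold from 1446 ± 21.7 to 757 ± 18.4 CPM (log2 -0.93, SE 0.055), beside PDIA4. DNAJB9, an ER co-chaperone and a carrier of the word, rose by 0.40 (edgeR adjusted p = 0.012; 0.218 without shWNK1 replicate 1 and 0.0655 without NS replicate 1). Heat shock genes comprised 12 falls, 0 rises and 4 members not called among 16 (12 fell adjusted over the list alone), with a median of -0.44 (camera adjusted p = 5.1e-08; adjusted p = 0.253 with an estimated correlation), led by HSPD1 and the small heat shock protein HSPB1 (-0.72). Proteasome subunits included 14 falls, 0 rises and 17 not called among 31 (14 fell adjusted over the list alone), with a median of -0.16, and PSMB5, a catalytic subunit, fell 2.08-fold (log2 -1.06). The camera call on the proteasome (adjusted p = 0.0021; adjusted p = 0.735 with an estimated correlation) ended without NS replicate 2 (0.0765) and with fry (0.0932). Without either shWNK1 library 7 of its members fell, and without NS replicate 1 there were 20 falls. ATF4 response genes went both ways, with 8 rises, including CHAC1 (1.56) and SESN2 (1.39; a carrier), and 6 falls, including WARS1 (-0.85) and TRIB3 (-0.72), among 25 (8 and 6 adjusted over the list alone; camera adjusted p = 0.581). Without either shWNK1 library there were 5 rises and 3 falls.

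Nuclear genes of oxidative phosphorylation had a median of -0.12, which was -0.26 without NS replicate 1 and -0.03 without NS replicate 2. Of 57, 16 fell, 2 rose and 39 were not called (16 and 2 adjusted over the list alone), with falls of COX6A1 (log2 -0.86) and ATP5PB (-0.42) and a rise of COX7C (0.73). That camera call (adjusted p = 0.0052; adjusted p = 0.735 with an estimated correlation) ended without NS replicate 2 (0.854) and with fry (0.341). Falls numbered 9 and 10 without shWNK1 replicate 1 and 2 and 34 without NS replicate 1, and without NS replicate 2 there were 8 rises. There was 1 rise without either shWNK1 library. Mitochondrially encoded mRNAs held 2 rises, those of MT-CO1 (0.27) and MT-ND4 (0.27), 2 falls and 9 members not called among 13 (2 and 1 adjusted over the list alone; camera adjusted p = 0.791; 0.0418 without NS replicate 1). Of its members 5 fell without NS replicate 2, and 1 fell when any other library was left out. Rises numbered 1 without shWNK1 replicate 1 and 0 without shWNK1 replicate 2. Without shWNK1 replicate 2 the adjusted p of MT-CO1 was 0.0849, and without either shWNK1 library that of MT-ND4 was 0.0505 to 0.0508. The mitochondrial rRNA share of counts was 1.01% (95% interval 1.00 to 1.01) and 1.10% (1.09 to 1.10) in shWNK1 and 0.471% (0.468 to 0.474) and 0.458% (0.455 to 0.462) in NS libraries. A part of library preparation in this difference was not tested.

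Most sterol and fatty acid synthesis genes fell. Among 24 cholesterol synthesis genes, 16 fell, 2 rose and 6 were not called (16 and 2 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 8.0e-05; adjusted p = 0.257 with an estimated correlation). The squalene epoxidase SQLE fell from 206 ± 12.1 to 132 ± 5.46 CPM (log2 -0.65, SE 0.065), and MVK (0.52) and TM7SF2 (0.62; edgeR adjusted p = 0.0089, and 0.126 without shWNK1 replicate 2, which left 1 rise) rose. Fatty acid synthesis genes held 8 falls, 0 rises and 4 members not called among 12 (9 fell adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.0011; adjusted p = 0.308 with an estimated correlation), and the desaturases SCD (-0.83) and FADS1 (-0.67), both carriers of the word, led them. There were 4 falls without shWNK1 replicate 1, and 1 rise without NS replicate 2. Glycolysis and hypoxia genes went both ways, with 8 rises, such as KDM3A (1.06), and 9 falls, such as the lactate dehydrogenase LDHA (-0.79), among 31 (8 and 10 adjusted over the list alone; camera adjusted p = 0.888). There were 5 rises without shWNK1 replicate 2.

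Autophagy genes were higher as a list. Of 37, 16 rose, 2 fell and 19 were not called (18 and 2 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.0011; adjusted p = 0.270 with an estimated correlation). The cargo receptor SQSTM1, a carrier of the word, rose from 668 ± 34.4 to 1167 ± 42.2 CPM (log2 0.80, SE 0.057, edgeR adjusted p = 5.0e-13), the initiating kinase ULK1 rose 1.91-fold (0.93), and TFEB, a transcription factor of lysosomal genes, rose 1.43-fold (0.52). Rises numbered 10 without shWNK1 replicate 1, and without NS replicate 1 or 2 there were 3 falls. ATG13 (-0.44) and ATG5 (-0.42) fell, and both were carriers of the word. Of 10 carriers in the list, 4 rose and 2 fell. Exons of SQSTM1 overlapped the opposite-strand gene MRNIP over 21.0% of their bases. Strand was not used, and the recorded command does not ask for reads over both genes to be counted. Lysosomal genes were split, with 10 rises, including CTSA (0.48), 8 falls, including CD63 (-1.06; a carrier), and 16 not called among 34 (10 and 9 adjusted over the list alone; camera adjusted p = 0.640). Without shWNK1 replicate 1 there were 6 rises, and without either shWNK1 library there were 3 falls. NRF2 targets were split as well, with 5 rises, among them FTH1 (0.85) and NQO1 (0.76; a carrier), and 5 falls, among them SRXN1 (-1.03; a carrier), of 14 (6 and 6 adjusted over the list alone; camera adjusted p = 0.640). There were 3 falls without shWNK1 replicate 2.

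Most NF-κB target genes rose. Of 17 NF-κB targets, 11 rose, 1 fell and 5 were not called (12 and 1 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 4.2e-05; adjusted p = 0.30 with an estimated correlation). Beside CXCL8, the deubiquitinase TNFAIP3 rose 2.25-fold (log2 1.17, SE 0.067), and NFKB1, which encodes the p50 precursor, fell 2.37-fold (-1.24). The 3′ UTRs of TNFAIP3 and NFKB1 were not searched. The growth arrest gene GADD45A rose 2.01-fold (1.01). Apoptosis genes comprised 12 rises, among them the BH3-only gene BMF (2.07), 7 falls, among them MCL1 (-0.45) and XIAP (-0.84), both carriers, and 8 not called among 27 (12 and 9 adjusted over the list alone; camera adjusted p = 0.329). Among genes with a searched 3′ UTR 12 rose and 5 fell (camera adjusted p = 0.0964), and among those lacking AGTATC, a word picked for its falling carriers, 11 rose and 3 fell (camera adjusted p = 0.019; adjusted p = 0.735 over all genes with an estimated correlation). Without NS replicate 1 there were 11 falls, and without shWNK1 replicate 2 there were 8 rises and 4 falls.

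Signalling, adhesion and immune lists were not called by camera over the tested genes. ERK immediate and feedback genes held 4 rises, including the phosphatase DUSP5 (1.57), and 3 falls, including SPRED1 (-1.51; a carrier), among 15 (4 and 3 adjusted over the list alone; camera adjusted p = 0.673; 0.0325 with fry). Their rises numbered 2 and their median was -0.37 without shWNK1 replicate 2, against 0.04 over all libraries. In the ERK5 cascade, 4 of 9 rose, such as MEF2D (0.81; a carrier), and 2 fell, such as MEF2C (-0.34; 4 and 2 adjusted over the list alone; camera adjusted p = 0.153; 0.0386 without a low-count filter and 0.0208 with fry). There was 1 fall without shWNK1 replicate 1 or NS replicate 1, where KLF2 lost its call (edgeR adjusted p = 0.295 and 0.321, and 0.0561 with the replicate block). Adhesion and migration genes included 5 rises and 3 falls among 22 (5 and 3 adjusted over the list alone; camera adjusted p = 0.888), with CD44 fallen 2.02-fold (-1.02). There were 3 rises without either shWNK1 library. Of 19 interferon-stimulated genes, 4 rose, among them PARP9 (1.00), and 2 fell, among them UBE2L6 (-0.58; 4 and 2 adjusted over the list alone; camera adjusted p = 0.420). Class I antigen presentation genes held 3 rises, among them HLA-E (0.64), and 6 falls, among them ERAP1 (-0.71; a carrier), of 15 (3 and 6 adjusted over the list alone; camera adjusted p = 0.390).

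Plasma cell genes changed in both directions, with more falls than rises. SDC1, the plasma cell marker CD138, fell from 217 ± 11.5 to 86.7 ± 6.63 CPM (log2 -1.32, SE 0.069, edgeR adjusted p = 3.3e-16) and the elongation factor ELL2, a carrier of the word, fell by 0.92, while SLAMF7 and the coactivator POU2AF1 (0.83) rose. Changes of the identity factors were small: IRF4 fell by 0.23 (edgeR adjusted p = 0.0014; 0.125 without shWNK1 replicate 1), PRDM1 rose by 0.25 (0.0011; 0.0575 without shWNK1 replicate 1), and XBP1 fell by 0.17 (0.020; 0.0726 with upper-quartile factors, 0.208 without shWNK1 replicate 1 and 0.174 without shWNK1 replicate 2). TNFRSF17, the receptor BCMA, was at 34.3 ± 1.15 CPM in shWNK1 and 29.2 ± 1.71 CPM in NS cells (edgeR adjusted p = 0.0865; 0.0431 with upper-quartile factors and 0.0485 without NS replicate 1). The list of 20 held 5 rises and 10 falls (6 and 10 adjusted over the list alone; camera adjusted p = 0.158; 0.0182 without NS replicate 1, 0.0384 with fry and 0.0271 without a low-count filter). Without shWNK1 replicate 1 there were 2 rises and 5 falls, and without shWNK1 replicate 2 there were 6 falls. The transcription factor MAF fell by 0.30 (edgeR adjusted p = 5.1e-05), whereas its associated genes CCND2 (0.44; a carrier) and ITGB7 (0.63) rose. Over 42.3% of its exonic bases ITGB7 overlaps the opposite-strand gene ZNF740, and the recorded command does not ask for reads over both to be counted. That list of 8 held 4 rises and 2 falls (4 and 3 adjusted over the list alone; camera adjusted p = 0.329; 0.0215 with fry).

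Immunoglobulin and B-cell genes were divided. Some immunoglobulin heavy chain genes, such as the IGHG genes, are near-identical to each other, so their levels are uncertain. Of 9 immunoglobulin constant genes, 4 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.794): IGHE rose 2.51-fold and IGKC rose 1.20-fold (edgeR adjusted p = 7.9e-04; 0.0968 without shWNK1 replicate 1), and IGHG4 fell 2.74-fold and IGHG3 fell 1.51-fold. Without either shWNK1 library or NS replicate 2 there were 2 rises. Of 6 mature B-cell markers, SPIB (2.19), BCL6 (1.63) and CIITA (1.48) rose and PAX5 (-1.28; a carrier), CD79B (-0.39) and BACH2 (-0.25; a carrier) fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.535). There was 1 fall without shWNK1 replicate 1. The CD79B call (edgeR adjusted p = 0.021) ended with DESeq2 (0.0705) and without shWNK1 replicate 1 (0.372) or NS replicate 2 (0.0989). The BCL6 call (edgeR adjusted p = 0.0042) ended without shWNK1 replicate 1 (0.119). The BACH2 call (edgeR adjusted p = 0.049) ended without shWNK1 replicate 1 (0.338), shWNK1 replicate 2 (0.114) or NS replicate 1 (0.277). It ended too with DESeq2 (0.122), with upper-quartile factors (0.0994), without a low-count filter (0.0590) and with the replicate block (0.0721). Markers of other cell types were mostly too low to test: 3 of 12 T and NK, 2 of 11 myeloid, 0 of 8 erythroid and 3 of 11 stromal or epithelial markers passed the filter. S100A8 and S100A9 were the tested myeloid markers and both rose (2 adjusted over the list alone), while LYZ had 0 counts in all 4 libraries. KRT18 was the only call among the others (log2 -0.49, edgeR adjusted p = 0.027; 0.0925 with DESeq2, and 0.179, 0.105 and 0.140 without shWNK1 replicate 1, shWNK1 replicate 2 and NS replicate 2).

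**Figure D2:**
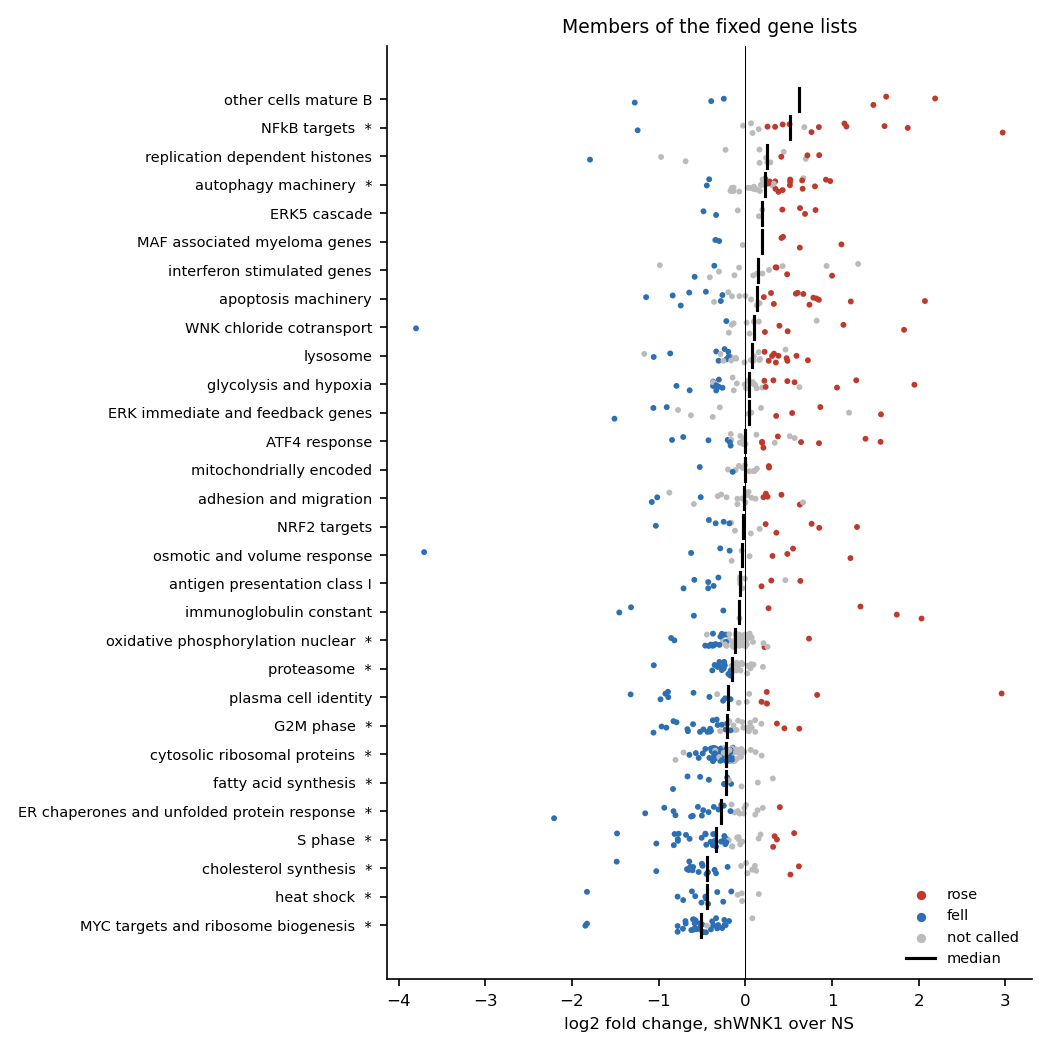
Log2 fold change (shWNK1 over NS) of each tested member of 30 of the 31 tested lists, ordered by list median (black bars); red points rose, blue points fell and grey points were not called by edgeR, and asterisks mark lists called by camera with the preset correlation. The median of MYC targets and ribosome biogenesis, -0.51, was the lowest, and that of NF-κB targets, 0.51, was the highest among lists called.

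Camera called 13 of the 31 lists, 3 higher and 10 lower, and 0 with an estimated correlation (5 at an unadjusted p under 0.05). That setting also missed a simulated shift, but the simulated genes varied independently, so this does not justify the preset correlation. The estimated correlation was 0.850 for cytosolic ribosomal proteins, 0.557 for nuclear oxidative phosphorylation genes and 0.367 for the proteasome, against the preset 0.01. Fry did not call those lists. In the other called lists the estimate was at most 0.084. Fry called 14. Examples from lists that were not called were chosen after their values were seen. Of the lists called, not all are described here. The median, mean and camera direction did not share a sign in the osmotic, lysosome, ERK, adhesion, glycolysis, mitochondrially encoded, NRF2 and immunoglobulin lists, none of which was called.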

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

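The fits to genes with a searched 3′ UTR, and to those lacking AGTATC, were chosen after seeing the data. The total of 5760 changed genes stayed between 4488 and 5826 under the other tests, size factors and filters and with immunoglobulin and mitochondrial genes left out, and no gene called in the main analysis had the opposite sign in any alternative. With the replicate number as a block 5343 genes changed, 5324 of them also called without it. The deviations of replicate 1 in the groups had a correlation of -0.0047 over 14864 genes. No shift shared by replicates of the same number was thus seen, which does not tell how they were prepared. Against a 1.5-fold change 656 genes passed, 303 rising and 353 falling, because that test asks for more. Leaving out 1 library, where a lone library is assumed to vary like the other group, gave 3627 to 5709 changed genes, 1632 to 2778 rises and 1964 to 3024 falls, lowest without a shWNK1 library. Among genes lacking AGTATC fewer genes were tested (8762) and 1867 fell. Upper-quartile factors moved the median of all genes to 0.044 and gave 54.1% rises among calls, against 47.8%. An estimated correlation called 0 lists (0 higher and 0 lower), and fry called 14, of which 6 higher; without NS replicate 1 there were 15 and without NS replicate 2 there were 11. WNK1 stayed between -3.91 and -3.68 with any library left out. Direction reversed for results that were not called, and the cause was not tested: WNK2 (-0.11 to 0.16 with a library left out), and, as adjusted p, the WNK list (0.336 to 0.934), adhesion (0.623 to 0.978; fry 0.773; genes lacking AGTATC 0.982), glycolysis (0.482 to 0.928; DESeq2 0.990; upper-quartile 0.971; genes with a searched 3′ UTR 0.982) and mitochondrially encoded genes (0.0418 to 0.854). Over all alternatives, named genes kept direction and call in 938 fits, lost the call in 45, gained it in 3 and reversed in 2, and lists did so in 420, 18, 9 and 11. Depth limits genes near the floor of 3 counts (0.149 to 0.177 CPM), where recovery was not simulated. In the simulation 44% of the smallest changes, planted only in genes of at least 5 CPM, were recovered.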

Other observations

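The test for carry-over of myeloid cells, the comparison of genes lacking AGTATC, the removal of length and GC trends and the gene families described here were chosen after the results were seen.

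A word was more frequent in the 3′ UTRs of transcripts that fell, though most of them lacked it. Of 16129 words of 7 bases tested, AAGTATC had the lowest z (-19.98 by linear regression on normal scores of ranks, n = 10521 genes, Bonferroni p = 1.4e-84). Among the other 9 lowest words 5 overlapped it by 6 bases, and the lowest unrelated word, TCACAAA, had a z of -4.27. The median log2 fold change was -0.37 (95% interval -0.45 to -0.27) for 301 genes with AAGTATCA, -0.21 (-0.25 to -0.16) for 540 with AAGTATC, -0.13 (-0.19 to -0.11) for 539 with AGTATCA, -0.03 (-0.06 to -0.00) for 862 with AGTATC alone and 0.02 (0.01 to 0.03) for 8279 with none. These medians, and the shares of genes with AGTATC, were not adjusted for 3′ UTR length. Its median was 2683.5 to 3331.5 bases in the classes with the word and 854 in the class with none. A candidate explanation for part of the falls is that the hairpin's strand acts on partly matching transcripts as a microRNA would. The coding part of WNK1 holds AAGTATC at 2997 to 3003 and 4885 to 4891 of its transcript of 10452 bases. A word of 7 bases can occur by chance in a transcript that long, so this match is weak evidence. The share of falling genes with AGTATC, 32.0% (95% interval 30.2 to 33.8), argued against direct action through that word in 3′ UTRs on every falling gene. That share cannot address falls that follow from those of carriers. Among genes that fell at least 2-fold the share was 57.8% (51.4 to 64.0). The 10 lists called lower over all genes were called lower among genes lacking the word too, with the preset correlation. With an estimated one 0 lists were called over all genes. Genes lacking AGTATC can still hold related words, such as TGTATCA (z of -9.89 in the same regression), or sites outside the searched 3′ UTR. For such sites these values decide nothing. The hairpin sequence was not used here, a small RNA of the cell with that seed was not tested, and falls of genes without the word may follow from loss of WNK1 or from other transcripts that fell.

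Ribosomal protein transcripts were lower by a median of -0.22, which was -0.30 without NS replicate 1 and -0.11 without NS replicate 2, so its size rests in part on NS replicate 2. With a trend in gene length removed from each library the median was -0.2133 (SD of members 0.169, 49 of 77 fell). With a trend in GC content removed it was -0.2143 (SD 0.164, 47 fell). Both trends were weak over all genes (Spearman 0.070 for length and 0.049 for GC). The list's median GC content, 49.0%, was near the 48.6% of all genes, so removing the GC trend could move the list little. Gene length joins all annotated exons and is not that of the mRNA, so a bias by mRNA length was not tested. A fall in ribosome production after that of MYC may be one explanation, and reads lost to pseudogenes or a technical difference of NS replicate 2 others, and none of these was tested.

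Carry-over of myeloid cells was considered for the rises of CXCL8, S100A9 and LTF. LYZ and FCN1, abundant in such cells, had 0 counts in every library, and LYZ, CD14, FCN1 and CSF1R together came to 0.04545 of S100A9 in the shWNK1 library where that ratio was higher, which argues against it. The rise of LTF, 4.12-fold, was counted as 667 and 931 against 168 and 177. A change within JJN3 cells may explain these rises and was not tested.

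Class II antigen presentation genes rose in 7 of 9 cases, among them CIITA (log2 1.48), HLA-DRA (0.76), HLA-DPA1 (0.69) and CD74 (0.62), while HLA-DMA (edgeR adjusted p = 0.0544; 0.0026 without NS replicate 1, 0.0451 with limma-voom, 0.0333 with upper-quartile factors and 0.0470 among genes with a searched 3′ UTR) and HLA-DMB (0.207) were not called. IL10 (1.46), CXCL12 (1.86) and CCR2 (1.80) rose. Of 9 polyamine genes 4 fell, 3 rose and 2 were not called. The synthesis enzymes fell, ODC1 by 1.85 and AMD1 by 0.58, both carriers of the word AGTATC, SRM by 0.49 and SMS by 0.30, whereas SMOX, which oxidises spermine, rose (1.92). OAZ2 (0.35; edgeR adjusted p = 0.0036, and 0.0778 without shWNK1 replicate 1) and AZIN1 (0.22; 0.0027, and 0.0719 and 0.0906 without shWNK1 replicate 1 and 2) rose, and SAT1 (0.386) and OAZ1 (0.256) were not called. The chromatin proteins HMGN4 (-1.79), HMGB2 (-1.59), HMGN2 (-1.39), HMGB3 (-0.78) and HMGB1 (-0.57) fell, all but HMGB3 with AGTATC in the 3′ UTR. The other members of that family lack the word: HMGN3 fell (-0.22, edgeR adjusted p = 0.021), a call that ended with DESeq2 (0.0614), upper-quartile factors (0.0608) and the replicate block (0.0560), and without shWNK1 replicate 1 (0.0600), shWNK1 replicate 2 (0.335) or NS replicate 2 (0.202). HMGN1 was not called (-0.15, edgeR adjusted p = 0.0564; 5.6e-04 without NS replicate 1, 0.0456 among genes with a searched 3′ UTR and 0.0479 among those lacking AGTATC). The mitochondrial rRNAs MT-RNR1 (0.80) and MT-RNR2 (1.16) rose. Whether these rises reflect the cells or the preparation of the libraries was not tested.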
